A study of Arabidopsis thaliana with 12 samples.

How the data were processed

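Poly-A RNA of whole Arabidopsis thaliana seedlings of the accession Col-0 was sequenced in 12 stranded libraries. The labels place 3 libraries in each of 4 groups: wild type (WT) and a stable 35S:HIN1 line (HIN1), each kept at a water potential of -0.25 MPa (control) or moved to agar infused with polyethylene glycol at -0.7 MPa (stress). Per the labels, seedlings were moved after 7 days and harvested 96 h later, and the 3 libraries of a group came from 3 separate experiments and RNA extractions. Per the design text of the series, the WT libraries also serve another series on a different mutant. The 35S promoter of cauliflower mosaic virus drives expression in most plant tissues, and HIN1 is the gene AT3G11290.

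The authors deposited 1 table per library with reads per gene, RPKM and the share of reads that mapped to several sites. Per the submitters' processing notes, the tools were CASAVA with bcl2fastq 1.8.4, Trimmomatic 0.35, Bowtie2 and DESeq2, and the build was TAIR10. The counting tool, the annotation release and whether counting used the strand are not given in the sources used here. The deposited reads per gene are expected counts, per the file headers and the values: 4.09% to 4.56% of genes held fractional values, and these lay in genes with reads at several sites. The deposited RPKM values were used only to recover the total that the authors divided by, which was 62.75 M to 73.86 M per library, and the gene reads made up 92.42% to 93.16% of it. The deposited fraction of reads at several sites was used to mark genes whose reads are shared, and 1.33% to 2.6% of all gene reads were of this kind. The authors' 3 deposited comparison tables give a log2 fold change with its standard error and a p-value with its adjusted value per gene, per the file headers, and DESeq2 is the only test tool in the processing notes.

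The deposited counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr at its defaults over the 4 groups, with a minimum count of 10, which left 22924 of 33602 genes. Library sizes were scaled with TMM factors, which ran from 0.947 to 1.033. All 12 libraries entered 1 quasi-likelihood fit with a coefficient per group and 8 residual degrees of freedom. The common dispersion was 0.01701, a biological coefficient of variation of 13.04%. Tests were two-sided glmQLFTest contrasts with Benjamini-Hochberg adjustment over all genes tested, and a gene was called below an adjusted p of 0.05 with no fold threshold. Every adjusted p given for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. Levels are CPM, read counts scaled to the TMM-adjusted library size, given as mean ± SD over n = 3 libraries. An error beside a log2 fold change is an approximate standard error. It is the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. This error can be inaccurate for genes near 0 CPM in a group. There were 4 pairwise comparisons and the interaction, which is the stress response of HIN1 less that of WT. The p-values measure the spread between experiments of 1 line per genotype, so another transformed line could differ.

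The 24 gene lists hold 405 genes: ABA and dehydration response, proline metabolism, clade A PP2C phosphatases, ABA receptors, SR splicing factors, light harvesting and Rubisco small subunit, expansins and XTH wall enzymes, cell division, flavonoid and anthocyanin pathway, salicylic acid and pathogen response, jasmonate and ethylene response, glucosinolate biosynthesis, phosphate starvation, iron deficiency, heat shock, senescence and dark induced, aquaporins, cuticular wax, auxin response, root markers, root hair markers, guard cell and stomatal lineage markers, seed maturation markers and flowering regulators. Of their symbols 396 matched the reference names, 8 genes had no name there, and PRODH1 was listed under another name. Lists were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 24 lists of a comparison. Camera compares a list with the other genes. Camera with an estimated correlation and fry were run beside it. The directional p of fry tests whether the genes of a list move, on balance, one way, its mixed p tests whether they change in either direction, and neither compares the list with other genes. Each list also has a count of members adjusted over the list alone.

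Genes are named by a rule. It takes HIN1 and then the 6 highest and 6 lowest log2 fold changes, or 8 and 8 between genotypes, among called genes with a mean of at least 5 CPM over the libraries compared and no overlap between the libraries of the groups, an overlap that was not excluded for the interaction. It then takes up to 4 called members of each list in order of adjusted p, or, for a list with none, up to 2 of highest mean, given as values. A chance ordering leaves no overlap in 10% of genes with 3 libraries against 3. Genes without a symbol in the reference carry their locus identifier. The tests, the lists, this rule and the alternatives not marked as added were chosen before the data were examined.

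Gene names and coordinates come from the reference annotation of assembly TAIR10.1, in which 32835 of the 33602 genes matched by identifier. The submitters' build is TAIR10, and the file gives HIN1 a length of 1.696 kb against 1.806 kb of exons in the reference transcript, so the gene models are not identical. Because the strand of counting is not stated, the values of genes that overlap another gene are uncertain. The overlap of some such genes is given beside them in the report. The others named there overlap another gene over part of their length: UGT75C1 (14%), LHCB1.3 (8.8%), GSTF12 (8.7%), HSP17.4 (8%), TIP2;1 (7.1%), PAP17 (6.6%), FRK1 (4.5%), F6'H1 (4.3%), LHCB4.2 (3.2%), AT4G00700 (2.7%), THI2.1 (2.2%), P5CS1 (1.7%), EXPA7 (1.6%), RS31A (1.6%), WRKY33 (1%), AT5G18840 (0.9%) and CHS (0.1%). Overlaps concern 5 of the 47 genes named by fold change, 3 of them antisense, and 38 of the 159 named list members.

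Gene reads per library ran from 58 M to 68.56 M with a median of 61.6 M. Of 26458 values between 1 and 8 reads, 78.5% were even, with 2127 at 1 read and 10395 at 2 reads, while above 100 reads 50.1% were even. A count of 2 can thus be a single fragment, and an added alternative divided all counts by 2.

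The procedure was tested on counts simulated with the dispersions that edgeR estimated here and with 200 changed genes, 50 per fold size. In the simulated WT stress comparison (22728 genes) edgeR recovered 58% of genes changed 1.5-fold, 80% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 5.6% of its calls were false. In that of HIN1 and WT at control (22720 genes) it recovered 60%, 74%, 92% and 98%, with 1.8% false. For the interaction it recovered 22%, 62%, 78% and 96%, with 7.2% false. DESeq2 made 14.6%, 18.3% and 21.4% false calls in the same 3 simulations. A simulated list of 20 genes moved 1.5-fold was recovered by camera, camera with an estimated correlation and fry in each of the 5 comparisons. The genes of these lists were simulated independently, so the run cannot tell which of these tests suits lists of correlated genes.

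The alternatives were DESeq2 1.42.0, RLE factors, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, a fold of at least 2, fits to only the 6 libraries compared, each library left out in turn, and list tests with an estimated correlation. Chosen after seeing the data were the counts divided by 2, the libraries numbered 1 and 2 only, the list tests on those libraries and without WT control library 1, the runs of all settings for list members named in the report, and the runs without 1 library for gene families and neighboring genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.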

Results

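The transcriptomes of whole WT and 35S:HIN1 seedlings were compared at control water potential and after 96 h at -0.7 MPa, with 3 libraries in each of the 4 groups. The design asks how WT responds to low water potential, how ectopic HIN1 changes the transcriptome at each water potential, and whether it changes the response. Gene reads per library were 66.91 M, 61.06 M and 61.11 M in WT control, 68.56 M, 60.9 M and 58 M in WT stress, 62.19 M, 60.95 M and 60.94 M in HIN1 control, and 62.62 M, 64.78 M and 63.23 M in HIN1 stress. Within groups, pairwise correlations of log2 CPM across genes lay between 0.9837 and 0.9907. The first principal component (44.2% of variance) separated the treatments and the second (20.4%) the genotypes. WT control library 1 stood apart from the others on the third component (8.5%), with a score of 47 against 6.2 and -0.2 in the other WT control libraries. Reads of chloroplast genes were highest in library 3 of each group, at 0.408%, 0.589%, 0.75% and 0.479% of gene reads in WT control, WT stress, HIN1 control and HIN1 stress, against 0.141% to 0.263% in the other libraries.

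**Figure D1:**
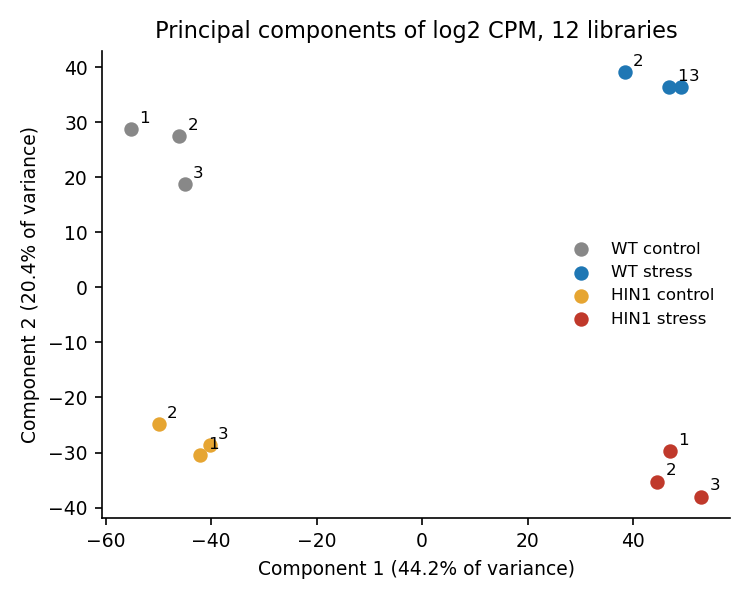
Scores of the 12 libraries on the first (44.2% of variance, x axis) and second (20.4%, y axis) principal components of log2 CPM. Each point is a library, colored by group and numbered by replicate. Control libraries lie between -55.2 and -40.3 on the first component and stress libraries between 38.4 and 52.9.

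HIN1 (AT3G11290; chromosome 3, 3535561 to 3537904 in TAIR10.1, 4 exons), a Myb/SANT-like DNA-binding domain protein gene, was present in WT at 24.53, 22.66 and 21.58 CPM in the control libraries and 23.58, 24.46 and 22.82 CPM in the stress libraries. In the HIN1 line its level was 249.59, 297.29 and 259.51 CPM at control and 315.55, 344.32 and 390 CPM at stress, so all 12 libraries carried the level their labels give. Its group means were 22.9 ± 1.49, 23.62 ± 0.818, 269 ± 25.2 and 350 ± 37.5 CPM (SD, n = 3) in WT control, WT stress, HIN1 control and HIN1 stress. The transcript was 11.7-fold higher in HIN1 than in WT at control (log2 fold change 3.55 ± 0.097, adjusted p = 5.08e-09) and 14.8-fold higher at stress (3.89 ± 0.098, adjusted p = 2.09e-09). It was not changed by stress in WT (0.04 ± 0.09, adjusted p = 0.751) and rose by 0.38 ± 0.087 in HIN1 (adjusted p = 0.00732), but the difference between these responses did not pass (0.34 ± 0.125, adjusted p = 0.496). Reads of the transgene and of the endogenous gene are counted together here.

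**Figure D2:**
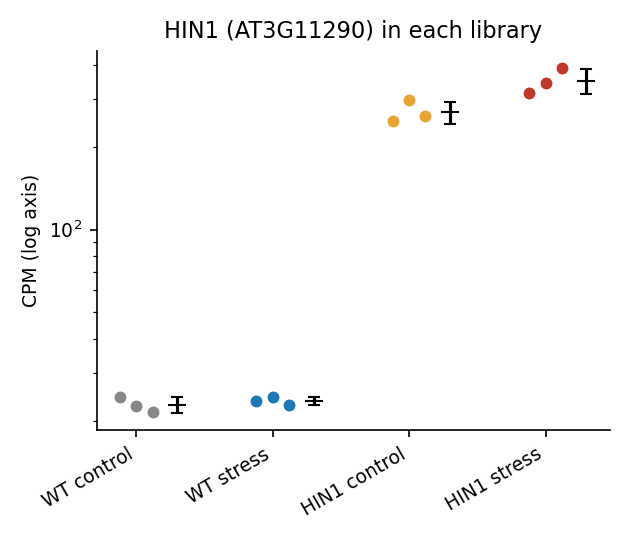
CPM of HIN1 (AT3G11290, y axis, log scale) in the 12 libraries by group (x axis). Points are libraries, and the bar beside them is the mean ± SD of n = 3. The HIN1 line lies between 249.59 and 390 CPM and WT between 21.58 and 24.53 CPM.

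In WT, low water potential raised transcripts of ABA and dehydration response and of anthocyanin synthesis, among single genes that of P5CS1, and lowered most ABA receptors. P5CS1, which encodes the rate-limiting enzyme of proline synthesis, went from 76.6 ± 10.7 to 741 ± 67.6 CPM (SD, n = 3), a log2 fold change of 3.28 ± 0.199 (adjusted p = 9.34e-07). PRODH1, which encodes the enzyme that starts proline breakdown, fell by 1.55 ± 0.136 (adjusted p = 1.1e-05). Of the 29 ABA and dehydration genes, 22 rose and 1 fell, and 24 rose and 2 fell when adjusted over the list alone. COR15A rose by 3.69 ± 0.187, RD20 by 3.38 ± 0.204 and the homeobox gene HB7 by 2.08 ± 0.137 on the log2 scale. The member that fell, CYP707A3, encodes an enzyme of ABA breakdown (-3.22 ± 0.769, or -1.56 without WT control library 1; named after its values were seen). Among the clade A PP2C phosphatases, negative regulators of ABA signaling, 7 of 9 rose (7 adjusted over the list alone), led by HAI2 (4.56 ± 0.263) and HAI1 (2.81 ± 0.224). Of 11 ABA receptors tested, 9 fell (9 adjusted over the list alone), among them PYL4 (-2.31 ± 0.126), PYL5 (-2.4 ± 0.159) and PYL6 (-3.99 ± 0.319). In the flavonoid and anthocyanin list 12 of 19 rose, or 13 adjusted over the list alone, including the regulator MYB75 (4.96 ± 0.417), the glucosyltransferase gene UGT75C1 (4.18 ± 0.442) and GSTF12 (4.51 ± 0.478), needed for anthocyanin transport. Camera adjusted p-values of these 4 lists were 3.48e-10, 1.12e-05, 6.12e-07 and 2.06e-07, with medians of 1.08, 0.86, -0.89 and 0.75. For each of them the adjusted p = 0.348 with an estimated correlation.

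Ranked by fold change, the highest genes in WT stress were AT2G16367 (0.0728 ± 0.0633 to 30.8 ± 13.9 CPM), LTP4 (6.90 ± 0.711), THI2.1 (6.32 ± 0.994), AT3G27250 (6.22 ± 0.335), NUDT24 (5.94 ± 0.641) and SWEET15 (5.53 ± 0.558), a sugar transporter gene. All 6 were below 1 CPM in WT control, so their folds rest on low counts there and are imprecise. The lowest were SWEET10 (-5.60 ± 0.385), the receptor-like kinase gene CRK30 (-5.45 ± 0.3), AT3G16670 (-5.13 ± 0.355; 108 ± 28.7 to 3.08 ± 1.66 CPM), the extensin-like gene AT1G26250 (-4.52 ± 0.268), AT5G17350 (-4.37 ± 0.948) and the cytochrome P450 gene CYP71B22 (-4.02 ± 0.397). Adjusted p-values of these 12 genes ran from 5.1e-07 (AT3G27250) to 0.00482 (AT5G17350). With 1 library left out, the log2 fold changes became 7.96 for LTP4, 8.22 for THI2.1 and 6.64 for NUDT24 (WT control library 2), 7.12 for AT3G27250 (WT control library 3), -2.88 for AT5G17350 (WT control library 1) and -4.82 for CYP71B22 (WT stress library 2).

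Camera placed 6 lists lower than other genes in WT stress. Light harvesting and Rubisco small subunit genes fell in 12 of 22 cases (13 adjusted over the list alone; median -0.40), with LHCA1 at -0.73 ± 0.117 and LHCB1.4 at -1.22 ± 0.246. Auxin response genes fell in 10 of 19 (11 adjusted over the list alone; median -0.49), including IAA19 (-1.36 ± 0.141) and IAA2 (-0.86 ± 0.138). Guard cell and stomatal lineage markers fell in 5 of 11 (5 adjusted over the list alone; median -0.20), including the potassium channel gene KAT1 (-1.28 ± 0.138) and MYB60 (-0.99 ± 0.147). Iron deficiency genes fell in 7 of 18 (9 adjusted over the list alone, median -0.77), including F6'H1 (-0.81 ± 0.187) and MYB72 (-4.12, adjusted p = 0.0193). MYB72 lost its call without WT control library 3 (-2.93, adjusted p = 0.0784), and 68.9% of its length overlaps a long noncoding RNA gene. Salicylic acid and pathogen response genes fell in 5 of 14 and rose in 1 (the same counts adjusted over the list alone; median -0.68). Here ALD1, which encodes an aminotransferase of pipecolic acid synthesis, fell by 3.76 ± 0.519, and PR2 rose by 4.03 ± 0.849, values of -4.41 and 3.29 without WT stress library 3. WRKY70 (-1.79 ± 0.476) and WRKY33 (-2.06 ± 0.548) lost their calls without WT control library 1 (-1.08 and -0.98, adjusted p = 0.0697 and 0.0679) or WT stress library 1 (0.0623 and 0.0585). Aquaporins fell in 7 and rose in 3 of 19 (11 and 3 adjusted over the list alone; median -0.22), with TIP2;1 at -1.43 ± 0.093, PIP1;5 at -1.15 ± 0.079 and PIP2;5 at 1.22 ± 0.11. Camera adjusted p-values of these 6 lists were 0.000112, 0.000788, 0.0241, 0.0219, 0.0241 and 0.0241. With an estimated correlation the adjusted p = 0.604, 0.48, 0.606, 0.636, 0.606 and 0.604. The calls of iron deficiency and aquaporins were lost on the libraries numbered 1 and 2 only. The mean log2 CPM of light harvesting genes was 11.38, 11.28 and 11.07 in the WT control libraries and 10.82, 10.93 and 10.84 in WT stress.

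Camera placed the cell division, heat shock, phosphate starvation and root hair lists higher than other genes in WT stress. Except in the phosphate starvation list, most members of each did not pass. Cell division genes rose in 11 of 24 (11 adjusted over the list alone; median 0.15), with CYCB1;1 at 0.50 ± 0.096 and CYCA1;1 at 0.41 ± 0.085. Heat shock genes rose in 5 of 13 (5 adjusted over the list alone; median 0.44), with HSP22 at 4.15 ± 0.451 and HSP17.4 at 1.94 ± 0.368. Phosphate starvation genes rose in 6 and fell in 2 of 13 (the same adjusted over the list alone; median 0.40), with the phosphatase gene PAP17 at 1.85 ± 0.099 and the transporter gene PHT1;4 at 0.86 ± 0.087. Root hair markers rose in 6 of 15 (7 adjusted over the list alone; median 0.67), with RHS10 at 1.2 ± 0.286 and EXPA7 at 1.52 ± 0.378 (2.25 without WT control library 3). The mean log2 CPM of that list was 0.757, 1.64 and 2.50 in the 3 WT control libraries and 2.32 to 2.87 in WT stress, so WT control library 1 was the lowest of these. Light harvesting and guard cell markers had medians of -0.40 and -0.20 against 0.67 for root hair markers, and root markers had a median of 0.04, so a change in the share of organs was not told from a change within them. Without WT control library 1 the camera adjusted p-values were 0.0206 for root hair, 0.000711 for light harvesting and 0.0234 for guard cell markers, and phosphate starvation lost its call (0.113), as it did on the libraries numbered 1 and 2 only. Camera adjusted p-values of these 4 lists were 0.00038, 0.0219, 0.046 and 0.000991. With an estimated correlation the adjusted p = 0.604, 0.606, 0.587 and 0.606.

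The other 10 lists were not called by camera in WT stress, although several held changed genes in both directions. Proline metabolism had 4 higher and 4 lower of 9 (5 and 4 adjusted over the list alone; fry adjusted p = 0.00128), with P5CDH (0.74 ± 0.064) overlapping SRO5 over 21% of its length. Jasmonate and ethylene response had 6 higher and 1 lower of 11 (6 and 2 adjusted over the list alone), including VSP2 (2.71 ± 0.216) and LOX2 (2.99 ± 0.35). Expansins and XTH wall enzymes had 8 higher and 12 lower of 33 (9 and 13 adjusted over the list alone), with XTH4 at -1.15 ± 0.071 and XTH24 at -1.66 ± 0.103. Cuticular wax had 5 higher and 7 lower of 17 (7 and 8 adjusted over the list alone), with LTP3 at 3.53 ± 0.19 and the alkane synthesis gene CER1 at 1.86 ± 0.138, and its median was -0.07 while its mean was 0.62. Glucosinolate biosynthesis had 6 higher and 6 lower of 24 (7 and 6 adjusted over the list alone; median 0.07, mean -0.13), with CYP79F2 at -1.12 ± 0.121 and MAM3 at -1.23 ± 0.142. Senescence and dark induced genes had 4 higher and 2 lower of 12 (the same adjusted over the list alone; median -0.02, mean 0.08), with DIN1 at -3.17 ± 0.429. SR splicing factors had 2 higher and 2 lower of 20 (2 and 1 adjusted over the list alone), and RS31A (0.35 ± 0.057) and SR45A (0.37 ± 0.068) were the higher ones. Root markers had 2 higher and 2 lower of 16 by edgeR, 0 adjusted over the list alone, 6 at an unadjusted p under 0.05 and 5 by DESeq2. Among them was WOX5 (0.78 ± 0.232), whose adjusted p was 0.0541 without WT control library 1, 0.0558 without library 2 and 0.113 without WT stress library 1. EM1 (2.97 ± 0.569) was the higher of 8 seed maturation markers and FT (-1.58 ± 0.352) the lower of 7 flowering regulators (median 0.07, mean -0.05), 1 gene each also adjusted over the list alone.

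In all, 7239 of 22924 genes (31.6%) changed in WT stress, 3416 up and 3823 down, with a median absolute log2 fold change of 0.508 among them. At a fold of at least 2 there were 1758, 679 up and 1079 down. Fry gave a directional call for 15 lists and a mixed call for 22 of the 24.

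**Figure D3:**
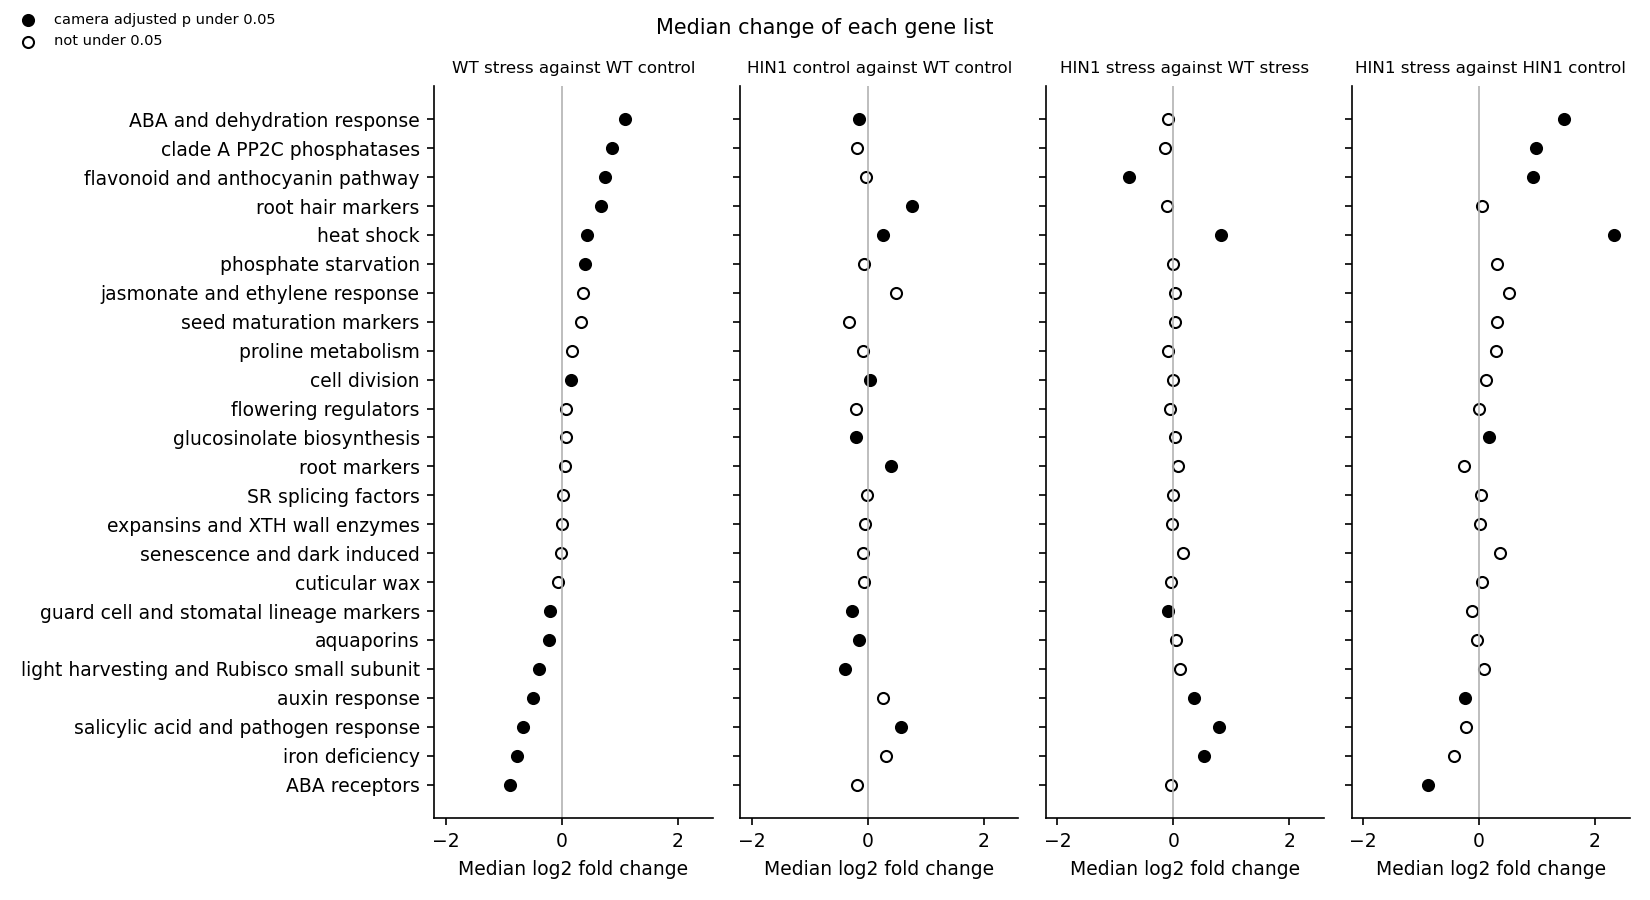
Median log2 fold change (x axis) of the tested members of each of the 24 gene lists (y axis) in the 4 pairwise comparisons, one panel each. Filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. ABA and dehydration response has medians of 1.08 in WT and 1.46 in HIN1 at stress against control, and root hair markers have 0.77 in HIN1 control against WT control.

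The HIN1 line responded to low water potential with 6219 changed genes, 3362 up and 2857 down, and 1519 of them changed at least 2-fold. P5CS1 rose by 3.38 ± 0.2, PRODH1 fell by 1.47 ± 0.136, COR15A rose by 3.74 ± 0.189, RD20 by 3.24 ± 0.204 and the galactinol synthase gene GOLS2 by 3.09 ± 0.223 on the log2 scale. ABA and dehydration genes rose in 25 of 29 (25 adjusted over the list alone; median 1.46). PP2C phosphatases rose in 7 of 9 (7 adjusted over the list alone; median 0.98; HAI2 4.48 ± 0.267), while ABA receptors fell in 8 and rose in 1 of 11 (the same adjusted over the list alone; median -0.87; PYL4 -2.13 ± 0.125). Heat shock genes rose in 8 of 13 (10 adjusted over the list alone; median 2.32), with HSP17.6C at 4.22 ± 0.402, HSP22 at 3.77 ± 0.395 and HSP23.6 at 5.05 ± 0.534 (5.67 without HIN1 control library 3). Flavonoid genes rose in 12 of 19 (12 adjusted over the list alone; median 0.93; MYB75 4.38 ± 0.418). Glucosinolate genes rose in 9 and fell in 3 of 24 (11 and 4 adjusted over the list alone; median 0.18), including MAM1 (0.73 ± 0.067), and auxin genes fell in 4 and rose in 1 of 19 (the same adjusted over the list alone; median -0.25; IAA19 -1.12 ± 0.14). Camera adjusted p-values of these 7 lists were 1.13e-12, 1.87e-05, 6.61e-06, 7.51e-05, 0.00251, 0.0161 and 0.0489. With an estimated correlation the adjusted p = 0.356 for the first 3 and 0.685 for the other 4, and auxin response also lost its call on the libraries numbered 1 and 2 only. Light harvesting genes had 3 higher and 2 lower of 22 here (the same adjusted over the list alone; median 0.09). Of 15 root hair markers, 0 passed by edgeR, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (median 0.06, mean -0.01).

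By fold change, AT3G42383 led in the HIN1 line, at 0.0323 ± 0.0316 CPM in control and 10.2 ± 2.61 CPM in stress, and its fold is imprecise at so low a control level. AT2G16367 (6.38 ± 0.484), LTP4 (5.31 ± 0.649), AT2G37870 (5.31 ± 0.269), AT3G27250 (5.24 ± 0.307) and THI2.1 (5.10 ± 0.933) followed. LTP4 was at 7.002 without HIN1 control library 3 and THI2.1 at 3.78 without HIN1 stress library 3. The lowest were AT3G16670 (-4.67 ± 0.347), AT1G26250 (-4.16 ± 0.236), PYL6 (-3.96 ± 0.321), CRK30 (-3.59 ± 0.256), the transporter gene UMAMIT17 (-3.44 ± 0.313) and the receptor-like kinase gene AT5G59680 (-3.19 ± 0.231). Among the 17 lists that camera did not call, proline genes had 5 higher and 3 lower, jasmonate and ethylene genes 6 and 1, phosphate starvation genes 6 and 1, aquaporins 5 and 6, guard cell markers 1 and 4, and salicylic acid genes 0 and 2, with the same counts adjusted over the list alone. Cell division had 7 higher (9 adjusted over the list alone), wall enzymes 10 higher and 10 lower (11 and 11; median 0.01, mean -0.11), wax genes 3 and 5 (6 and 5), and SR splicing factors 2 and 2 (1 and 1). Senescence genes had 5 higher and 1 lower (6 and 1), root markers 1 and 4 (1 and 5), and iron deficiency genes 0 and 4 (0 and 2). Among the iron deficiency genes, IRT1 lost its call without any library but HIN1 control 2 (highest adjusted p = 0.143, without HIN1 control library 1). EM1 (4.51 ± 0.618, or 5.23 without HIN1 control library 3) was one of 2 seed markers that rose, and the flowering regulator FUL (1.15 ± 0.318) lost its call without HIN1 control library 2 (adjusted p = 0.0667) or 3 (0.0725).

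The stress responses of the genotypes were positively correlated. Across 22924 genes, which are not independent replicates, the log2 fold changes of WT and HIN1 had a Pearson r of 0.706 and a Spearman rho of 0.709, and of the 9130 genes called in either, 94.1% had the same sign. Both genotypes raised 2231 of the same genes, where independent lists would share 501, and lowered 2077, where they would share 476.5, with 20 genes called in opposite directions. These comparisons share no library.

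At control water potential, 633 genes differed between HIN1 and WT, 501 higher (79.1%) and 132 lower, with genes of pathogen response among the higher ones. FMO1, which encodes the monooxygenase that makes N-hydroxypipecolic acid, went from 1.23 ± 0.396 CPM in WT to 16.7 ± 5.12 CPM in HIN1 (SD, n = 3), a log2 fold change of 3.76 ± 0.332 (adjusted p = 9.54e-05), and ALD1 from 0.524 ± 0.258 to 9.28 ± 1.82 CPM (4.15 ± 0.316, adjusted p = 3.07e-05). Camera called 10 of the 24 lists at control, while fry gave a directional call for 0 and a mixed call for 10. The salicylic acid and pathogen list had 3 of 14 higher, or 6 adjusted over the list alone (median 0.58, camera adjusted p = 4.17e-05, adjusted p = 0.594 with an estimated correlation). Its remaining called member, the salicylic acid synthesis gene ICS1 (0.53 ± 0.101), lost its call without HIN1 control library 1 (adjusted p = 0.0577) or 2 (0.0607). Next by fold change were AT5G38910 (3.00 ± 0.173), the germin-like gene GLP9 (2.55 ± 0.147; 6.81 ± 0.929 to 39.7 ± 3.23 CPM), AT3G28510 (2.92 ± 0.322), AT2G44370 (2.62 ± 0.147), AT2G39530 (2.59 ± 0.26) and the indole glucosinolate methyltransferase gene IGMT2 (2.39 ± 0.209), of whose reads 6.5% mapped to several sites. Outside that list, the chitinase gene CHIB (0.79 ± 0.094) rose in the jasmonate list, but 85.4% of its length overlaps an antisense long noncoding RNA gene.

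The lower genes at control were changed less. AT1G65845 (-1.25 ± 0.118, adjusted p = 0.000148, antisense to PAO4 over 7.3% of its length) and AT4G00700 (-1.23 ± 0.143, adjusted p = 0.000639) kept their calls without any 1 of the 6 libraries. The other 6 were AT1G66500 (-1.98 ± 0.373, or -1.30 without WT control library 1), DREB26 (-1.43 ± 0.316), the noncoding RNA gene AT1G67105 (-1.41 ± 0.33), the potassium transporter gene HAK5 (-1.37 ± 0.296; 49 ± 7.85 to 19.0 ± 6.1 CPM), SWEET10 (-1.37 ± 0.294) and PP2-A13 (-1.09 ± 0.247, antisense to PEX11E over 27.7%). Without HIN1 control library 1 their adjusted p-values were 0.074, 0.132, 0.158, 0.0996, 0.111 and 0.143, and without HIN1 control library 3 they were 0.0688, 0.118, 0.12, 0.104, 0.111 and 0.111. Without HIN1 control library 2 the calls of DREB26 (0.0631), AT1G67105 (0.112), SWEET10 (0.0647) and PP2-A13 (0.0539) were lost. Without WT control library 1 those of DREB26 (0.0953), AT1G67105 (0.112), HAK5 (0.0798), SWEET10 (0.0539) and PP2-A13 (0.138) were lost, and without WT control library 2 those of AT1G67105 (0.0772), HAK5 (0.0507) and SWEET10 (0.0743).

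All 15 root hair markers had positive log2 fold changes in HIN1 (median 0.77), although 0 passed by edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7, DESeq2 called 2, and the adjusted directional p of fry was 0.178. The 16 root markers had a median of 0.41 with 1 higher, or 5 adjusted over the list alone, and the nitrate transporter gene NRT2.1 rose by 2.14 ± 0.359 (adjusted p = 0.00713). Light harvesting and Rubisco small subunit genes had 2 of 22 lower, or 15 adjusted over the list alone (median -0.39). Of these, LHCB4.2 (-0.57 ± 0.121) lost its call without HIN1 control libraries 1 or 2 or WT control libraries 1 or 2 (highest adjusted p = 0.118). LHCB2.4 (-0.59 ± 0.135, overlapped over 37.6% of its length) lost it without HIN1 control libraries 2 or 3 or WT control libraries 1 or 2 (highest 0.169). Guard cell markers had 1 of 11 lower, or 2 adjusted over the list alone (median -0.26), the called gene being FAMA (-0.52 ± 0.079, adjusted p = 0.00375). Camera adjusted p-values were 8.14e-06 for root hair, 0.00258 for root, 3.88e-07 for light harvesting and 0.00077 for guard cell markers. For each the adjusted p = 0.594 with an estimated correlation. The mean log2 CPM of the root hair list was 2.28 to 2.65 in HIN1 control against 0.757, 1.64 and 2.50 in WT control.

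**Figure D4:**
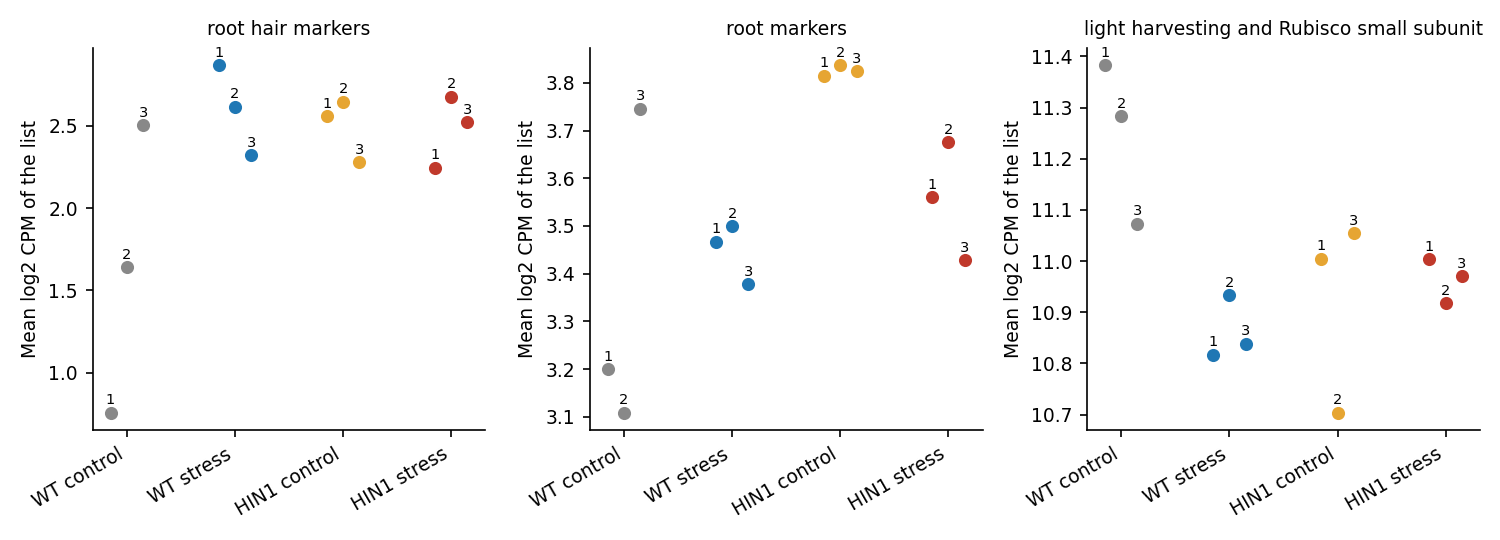
Mean log2 CPM (y axis) of root hair markers, root markers, and light harvesting and Rubisco small subunit genes in each library, by group (x axis). Points are single libraries, numbered by replicate. WT control library 1 has the lowest root hair value (0.757) and the highest light harvesting value (11.4).

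Glucosinolate biosynthesis had 2 of 24 lower, or 6 adjusted over the list alone (median -0.20, camera adjusted p = 0.000256, adjusted p = 0.594 with an estimated correlation). MAM1 (-0.36 ± 0.067) lost its call without HIN1 control libraries 2 or 3 or WT control library 1 (highest adjusted p = 0.0781), and MYB76 (-0.66 ± 0.145) without any library but WT control 3 (highest 0.154). Aquaporins had 1 of 19 lower, TIP2;2 (-1.06 ± 0.11), or 3 adjusted over the list alone (median -0.15, camera 0.00368, adjusted p = 0.594 with an estimated correlation). Cell division had 3 of 24 higher, MCM2 (0.32 ± 0.069), MCM4 (0.24 ± 0.052) and MCM6 (0.25 ± 0.056), or 6 adjusted over the list alone (median 0.04, camera 0.0241, adjusted p = 0.667 with an estimated correlation). Each of these 3 calls was lost without any library but WT control 3 (highest adjusted p = 0.112, 0.116 and 0.131). Heat shock (median 0.27, camera 0.0256) and ABA response (median -0.15, camera 0.0472) had 0 members called by edgeR, 1 and 0 adjusted over the list alone, and both had an adjusted p = 0.667 with an estimated correlation. Both calls were lost without WT control library 1 (0.209 and 0.0923). COR47 (-0.25 ± 0.127) and RD22 (0.01 ± 0.13) were the most abundant ABA response genes. Of the 14 lists without a camera call, 1 member each was called in jasmonate response (CHIB), senescence (SAG13, 1.79 ± 0.354), iron deficiency (F6'H1, 0.84 ± 0.185), wax (KCS1, 0.31 ± 0.069), wall enzymes (XTH24, -0.53 ± 0.101) and phosphate starvation (PHO1;H1, -0.48 ± 0.092). Adjusted over the list alone these lists also had 1 member each, except wax with 1 higher and 1 lower and wall enzymes with 1 higher and 5 lower. Apart from CHIB, these calls were lost in 3 or 4 of 6 runs with 1 library left out, with highest adjusted p-values of 0.0717, 0.128, 0.124, 0.0758 and 0.071, the first without WT control library 1, the last also, and the others without HIN1 control library 1. Jasmonate response had a median of 0.49 (mean 0.61) and iron deficiency of 0.32, each with a camera adjusted p of 0.0784. The phosphate list had a median of -0.06 and a mean of 0.06. SR splicing factors, proline metabolism, PP2C phosphatases, ABA receptors, flavonoid, auxin, seed and flowering lists had 0 members called by edgeR, with medians between -0.32 and 0.26, and 1 ABA receptor passed adjusted over the list alone. Median and mean differed in sign for PP2C phosphatases (-0.18 and 0.02) and flavonoid genes (-0.04 and 0.11). Over the 11 lists with 0 members called at control, 23 of 159 members had an unadjusted p under 0.05 and DESeq2 called 5.

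The number of genes called at control, and the share of higher ones, depended on single libraries. There were 2288 without WT control library 3 (1361 higher and 927 lower), 348 without WT control library 1 (319 and 29), and 370 (326 and 44) and 368 (323 and 45) without HIN1 control libraries 1 and 2. On the libraries numbered 1 and 2 only there were 1784 (1204 and 580). DESeq2 called 1486 genes (940 higher, 63.3%), a filter of 5 CPM in 3 libraries left 365, the 6 control libraries alone gave 300 (90.3% higher), and 328 had a fold of at least 2.

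At low water potential, 785 genes differed between HIN1 and WT, 740 higher (94.3%) and 45 lower, with pathogen response and heat shock genes among the higher ones. FMO1 went from 0.43 ± 0.298 CPM in WT stress to 24.9 ± 3.11 CPM in HIN1 stress (SD, n = 3; log2 fold change 5.88 ± 0.382, adjusted p = 4.28e-06) and ALD1 from 0.0378 ± 0.0275 to 2.17 ± 0.0887 CPM (5.80 ± 0.455, adjusted p = 1.69e-05), a fold that is imprecise because ALD1 was near the floor in WT stress. Without WT stress library 3, FMO1 was at 6.58, ALD1 at 6.46 and CYP71A13 at 4.55. The salicylic acid and pathogen list had 5 of 14 higher, or 6 adjusted over the list alone (median 0.78, camera adjusted p = 1.23e-07, fry adjusted p = 0.0111), and the adjusted p = 0.394 with an estimated correlation. CYP71A13 (3.15 ± 0.558), an enzyme gene of camalexin synthesis, overlaps IMA3 over 27.5% of its length, and FRK1 (1.47 ± 0.352) lost its call without any library but WT stress 3 (highest adjusted p = 0.136, without HIN1 stress library 3). Heat shock genes were higher in 5 of 13, or 9 adjusted over the list alone (median 0.82, camera adjusted p = 4.74e-07, fry adjusted p = 0.043, adjusted p = 0.394 with an estimated correlation). HSP17.6C went from 1.42 ± 0.28 to 17.0 ± 8.55 CPM (3.59 ± 0.385), HSP23.6 rose by 3.45 ± 0.473, HSP17.4 by 1.98 ± 0.338 and HSP18.2 by 1.54 ± 0.161. HSP17.6C was highest in HIN1 stress library 3, as was the mean of the heat shock list, at 3.76 log2 CPM against 2.76 and 3.02 in HIN1 stress libraries 1 and 2.

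The other genes with the highest fold changes at stress were AT3G42383 (0.148 ± 0.0693 to 10.2 ± 2.61 CPM; 6.05 ± 0.4), the berberine bridge enzyme-like genes AT1G26410 (5.69 ± 0.365, or 6.33 without WT stress library 3) and AT1G26420 (3.57 ± 0.129), and AT1G13480 of the DUF1262 family (3.83 ± 0.144). The fold of AT3G42383 is imprecise, since its level in WT stress was near the floor. Those with the lowest were EARLI1 (-2.85 ± 0.297; 9.99 ± 1.92 to 1.39 ± 0.209 CPM), AT1G67105 (-1.88 ± 0.324), THAS1 (-1.26 ± 0.187; 147 ± 7.1 to 61.2 ± 10.2 CPM), CYP705A5 (-1.12 ± 0.217), the beta-amylase gene BAM5 (-0.99 ± 0.17), AT5G18840 (-0.95 ± 0.143), CYP708A2 (-0.90 ± 0.172) and AT4G00700 (-0.87 ± 0.141). THAS1, CYP705A5 and CYP708A2 belong to the thalianol pathway, and the calls of CYP705A5 and CYP708A2 were lost without HIN1 stress library 1 (adjusted p = 0.0565 and 0.0527) or 3 (0.062 and 0.0585).

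**Figure D5:**
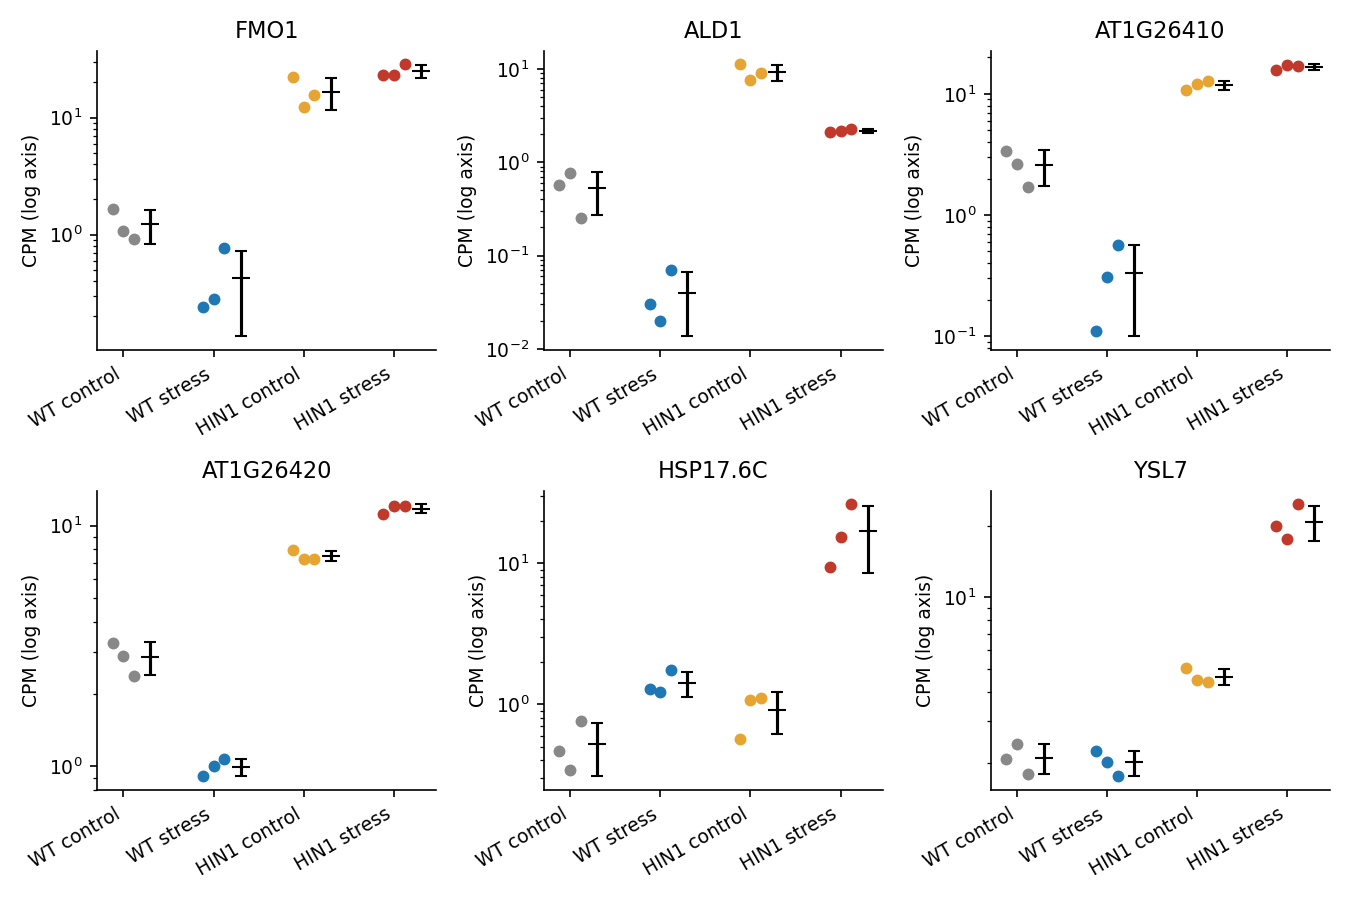
CPM (y axis, log scale) of FMO1, ALD1, AT1G26410, AT1G26420, HSP17.6C and YSL7 in each library by group (x axis). Points are libraries, and the bar beside them is the mean ± SD of n = 3. FMO1 is at 1.23, 0.43, 16.7 and 24.9 CPM on average in WT control, WT stress, HIN1 control and HIN1 stress.

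Among the other lists at stress, all 19 auxin response genes had positive log2 fold changes and 2 passed, or 3 adjusted over the list alone (median 0.35, camera adjusted p = 3.64e-05, adjusted p = 0.394 with an estimated correlation), GH3.2 (0.55 ± 0.093) and LBD16 (0.87 ± 0.157). Flavonoid genes had 18 of 19 negative values with a median of -0.76 and 0 called by edgeR, also adjusted over the list alone (camera 6.22e-07, adjusted p = 0.394 with an estimated correlation), with CHS at -0.47 ± 0.176 and FLS1 at -0.26 ± 0.108. Iron deficiency genes had 18 of 18 positive values with a median of 0.52 (camera 0.00757), with 0 called by edgeR and 1 by DESeq2. Guard cell markers had a median of -0.09 (camera 0.0452), with 0 called by edgeR and 0 by DESeq2. Both lists had an adjusted p = 0.925 with an estimated correlation and lost their camera calls on the libraries numbered 1 and 2 only. Root hair markers had a median of -0.10, root markers of 0.09 and light harvesting genes of 0.11, with 0 called by edgeR and no camera call, while at control these lists had 0.77, 0.41 and -0.39. Called members of lists without a camera call were SAG13 (2.91 ± 0.362), CHIB (0.94 ± 0.093), PYL3 (1.48 ± 0.318), PIP1;1 (0.36 ± 0.08), TIP2;2 (-0.46 ± 0.109) and CYP81F2 (1.51 ± 0.355). Adjusted over the list alone these lists had the same counts, except jasmonate response with 2 higher. The last 4 lost their calls in 4 or 5 of 6 runs with 1 library left out, with highest adjusted p-values of 0.105 (without HIN1 stress library 2), 0.143 (without WT stress library 1), 0.175 (without HIN1 stress library 3) and 0.173 (without HIN1 stress library 2). The ABA response, proline, PP2C phosphatase, SR splicing factor, wall enzyme, cell division, phosphate starvation, wax, seed and flowering lists had 0 members called by edgeR, with medians between -0.14 and 0.03. Adjusted over the list alone, 1 phosphate starvation gene was higher and 1 lower and 1 seed marker was higher. Median and mean differed in sign for ABA receptors (-0.04 and 0.07), wall enzymes (-0.02 and 0.02) and cell division (-0.01 and 0.00). Over the 16 lists with 0 members called at stress, 45 of 270 members had an unadjusted p under 0.05 and DESeq2 called 5. Fry gave a directional call for 2 of the 24 lists at stress and a mixed call for 9. With a filter of 5 CPM in 3 libraries 313 genes were called at stress.

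The effects of the HIN1 line at control and at stress were positively correlated. Across 22923 genes other than HIN1, Pearson r was 0.521 and Spearman rho 0.205, and over the 16745 genes of 5 CPM or more they were 0.309 and 0.111. Of 1105 genes called in either comparison, 89% had the same sign. The comparisons shared 295 higher genes, HIN1 included, where independent lists would share 16.2. They shared 16 lower genes against 0.259, and 1 gene was called in opposite directions. The mean stress effect and the mean genotype effect had an r of 0.089 and a rho of -0.013 across genes, and an r of -0.067 among genes of 5 CPM or more.

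The stress response differed between the genotypes in 36 genes, 35 with a more positive response in HIN1. Without WT control library 3 there were 238, 102 more positive and 136 more negative, so the excess of more positive responses depended on that library. By the naming rule these were AT1G26410 (difference of log2 fold changes 3.5 ± 0.459, adjusted p = 0.0119; 4.12 without WT stress library 3), the bHLH gene AT2G43140 (3.06 ± 0.344, adjusted p = 0.00485), AT1G26390 (2.83 ± 0.449, adjusted p = 0.0374), the camalexin pathway gene CYP71A12 (2.4 ± 0.338, adjusted p = 0.0177), the transporter gene YSL7 (2.23 ± 0.212, adjusted p = 0.00155) and AT1G26420 (2.17 ± 0.17, adjusted p = 0.000688). CYP71A12 was at 45.6 ± 7.2 and 7.57 ± 2.61 CPM in WT control and stress, and at 41.1 ± 7.76 and 35.9 ± 8.28 CPM in HIN1. YSL7 was at 2.1 ± 0.31 and 2.01 ± 0.245 CPM in WT and at 4.62 ± 0.34 and 20.9 ± 3.61 CPM in HIN1. AT2G43140 was at 7.24 ± 2.37 and 0.514 ± 0.0664 CPM in WT and at 9.46 ± 2.29 and 5.63 ± 0.402 CPM in HIN1. BAM5, named after its values were seen as the only gene with the opposite sign when all 12 libraries were used, was at 0.635 ± 0.143 and 11.2 ± 1.66 CPM in WT and at 1.32 ± 0.208 and 5.66 ± 0.823 CPM in HIN1 (-2.05 ± 0.268, adjusted p = 0.0119, or 0.0509 without WT stress library 1). AT1G26390 lost its call without each library except WT control 3 (highest adjusted p = 0.124, without WT stress library 3), AT1G26410 without HIN1 control library 3 (0.0546), and CYP71A12 without HIN1 control library 2 (0.0644) or 3 (0.0727) or WT stress library 2 (0.0529). The 36 genes became 12 without HIN1 control library 3, 13 without WT stress library 1, 18 without HIN1 stress library 3, 19 without WT stress library 3, 20 without HIN1 control library 2, and 23 without WT control library 2 or WT stress library 2. On the libraries numbered 1 and 2 only, 8 genes were called, 4 in each direction. DESeq2 called 195, 172 of them more positive, and a filter of 5 CPM in 3 libraries left 18.

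Of 393 list members, 0 passed in the interaction by edgeR over all genes, 67 had an unadjusted p under 0.05 and DESeq2 called 11, of which 6 were light harvesting genes. Adjusted over the list alone, 14 light harvesting genes, 3 heat shock genes and 1 gene each of the salicylic acid, glucosinolate and aquaporin lists passed, all with a more positive response in HIN1. Camera called 9 lists. Light harvesting (median difference 0.49, adjusted p = 7.13e-09), glucosinolate (0.22, 8.47e-06), aquaporins (0.21, 0.00213), heat shock (0.74, 0.00684) and auxin response (0.27, 0.0178) were more positive in HIN1. Root hair markers (-0.89, 8.45e-07), flavonoid genes (-0.47, 1.73e-05), root markers (-0.34, 0.00535) and cell division (-0.06, 0.0257) were more negative. With an estimated correlation the adjusted p = 0.675 for light harvesting, glucosinolate, aquaporins and flavonoid genes, 0.677 for root hair markers, 0.686 for heat shock, auxin and root markers, and 0.857 for cell division, and fry called 0 of the 24 lists in either way. Heat shock also lost its call on the libraries numbered 1 and 2 only. The wax list, without a call, had a median of 0.02 and a mean of -0.05. The most abundant members were LHCB1.3 (0.45 ± 0.194) and RBCS1A (0.01 ± 0.163) in the light harvesting list and XTH14 (-0.97 ± 0.488) and PRP3 (-0.98 ± 0.461) in the root hair list. The root hair values rest on the same WT control libraries as above, of which library 1 was lowest.

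The authors' deposited tables, made with their own settings, listed 6352 genes with an adjusted p under 0.05 in WT stress against control (2981 higher, 3371 lower), 1090 in HIN1 against WT at control (751 and 339), and 1115 at stress (977 and 138). Of these, 2820 higher and 3190 lower genes in WT stress, 475 and 115 at control, and 696 and 42 at stress were also called here in the same direction, and 0 were called in opposite directions. In the authors' deposited tables HIN1 had log2 fold changes of 3.297 at control and 3.36 at stress, while the largest absolute log2 fold changes of any gene were 5.24 in WT stress, 3.3 at control and 3.36 at stress. Whether these were shrunken was not stated, so they were not compared with the 3.55 and 3.89 found here.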

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

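The tests of root content, and the sorting of other splits by the libraries they exchange, were chosen after the results were seen. The stress response differed between HIN1 and WT in 36 genes by the test of the interaction. The log2 differences of the responses, HIN1 less WT, were 3.5 for AT1G26410, 3.06 for AT2G43140, 2.83 for AT1G26390, 2.4 for CYP71A12, 2.23 for YSL7, 2.17 for AT1G26420 and -2.05 for BAM5, the last named after its values were seen. Of the 36 genes, 25 fell in WT stress and 21 rose in HIN1 stress. The 35 genes with a more positive response in HIN1 were all higher in HIN1 stress than in WT stress. The selection partly builds in these counts. Without WT control library 3 there were 238 genes, 102 more positive and 136 more negative in HIN1. The excess of more positive responses thus depended on that library. Of 200 possible splits that exchange libraries between the genotypes within each treatment, 100 were drawn. As many genes were called in 8 of these 100, the real split included. This share is not a chance rate, because such splits can carry the genotype effect into the interaction. The highest other count was 1288, from the split that swaps the genotypes at a single treatment, which turns the genotype effect into an interaction and so points to the structure of the samples. Without that split the highest other count was 99 and the median was 0. Of the 7 other splits with as many genes, 6 were all those drawn that exchange 2 of 3 libraries at control and 0 at stress, counting mirrors as the same, with 45 to 99 genes. These 6 keep the genotypes whole at stress and swap most of them at control. Part of the genotype effect thus enters their interaction as well. The 4 drawn that exchange 2 of 3 at stress and 0 at control had 0 genes each, though they mix the genotypes as much, and the reason for this difference was not tested. Of the remaining 88 splits the highest had 22 genes. Whether chance gave the 36 genes stays open, since the splits give no chance rate for this count.

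The lists that camera called in the interaction had median log2 differences of 0.49 for light harvesting and Rubisco small subunit, 0.22 for glucosinolate biosynthesis, 0.21 for aquaporins, 0.74 for heat shock, 0.27 for auxin response, -0.89 for root hair markers, -0.47 for flavonoid and anthocyanin genes, -0.34 for root markers and -0.064 for cell division. With an estimated correlation 0 of the 24 lists were called. The lists of roots and of light harvesting also moved in opposite directions between HIN1 control and WT control. There, 28 of 31 root and root hair markers (90.3%) had positive log2 fold changes in HIN1. Of the light harvesting and guard cell markers, 32 of 33 (97%) had negative ones. A larger share of root RNA in the HIN1 control libraries would give such signs. It would also move root hair and other root markers alike. Their quartile ranges overlapped only in part (0.56 to 0.862 and 0.139 to 0.678), with medians of 0.765 and 0.411. A single WT control library as the whole cause was argued against, since the median of the root hair markers was at least 0.435, the value without WT control library 1, and was 0.675 without library 2 and 1.38 without library 3. Uneven root content among the WT control libraries stays open, because the mean root hair level, 1.63 (SD 0.873) log2 CPM in WT control and 2.50 (SD 0.191) in HIN1 control, differed with an exact two-sided permutation p of 0.2 where 0.1 is the smallest that 3 against 3 libraries allow. An effect of the HIN1 line on root growth could give the same values and was not tested.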

How the results depend on the processing

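The libraries numbered 1 and 2 only, camera without WT control library 1, the counts divided by 2 and the runs for list members named in the report were chosen after seeing the data. HIN1 kept its direction and call in all settings, with log2 fold changes of 3.47 to 3.62 at control and 3.80 to 3.96 at stress when 1 library was left out. With a fold of at least 2 the count of changed genes was 1758 in WT stress, 328 in HIN1 control against WT control and 1519 in HIN1 stress against HIN1 control, fewer because a further threshold was added. DESeq2 called 1486 genes at control and 195 in the interaction, and the cause was not tested. In the simulations DESeq2 made 39 false calls against 3 by edgeR at control, and 39 against 10 in the interaction. The simulations used dispersions that edgeR estimated, so they do not tell whether the additional DESeq2 calls are false. The filter of 5 CPM in 3 libraries gave 365 at control, 313 at stress and 18 in the interaction, with fewer genes tested. Only the 6 control libraries gave 300 at control. The libraries numbered 1 and 2 only gave 1784 at control, 378 at stress and 8 in the interaction (4 in each direction), and the cause was not tested. With 1 library left out, the count ran from 5136 to 7546 in WT stress, from 348 (without WT control library 1) to 2288 (without WT control library 3) at control, from 536 to 695 at stress, from 4591 to 4985 in HIN1 stress against HIN1 control, and from 12 (without HIN1 control library 3) to 238 (without WT control library 3; 102 more positive and 136 more negative) in the interaction. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 14, 10, 6, 7 and 9 at the preset correlation. On the libraries numbered 1 and 2 it called 11, 11, 8, 6 and 9. There, HIN1 at control gained iron deficiency, HIN1 at stress gained ABA response, PP2C phosphatases, glucosinolate and root hair, and the interaction gained guard cell markers. Without WT control library 1 it called 13 in WT stress, 9 at control and 10 in the interaction, the last 2 with seed maturation markers gained. Among genes of 5 CPM or more the correlation across genes between the HIN1 effects was 0.309, and that between the stress and genotype effects was -0.067, reversed from 0.089, and the cause was not tested. With the replicate number as a block the counts were 7330, 540, 725, 6322 and 27 genes and 13, 10, 6, 8 and 9 lists, in the order WT stress, HIN1 at control, HIN1 at stress, HIN1 stress and interaction. The lists that differed were phosphate starvation (lost in WT stress), ABA response (lost at control), jasmonate response (gained at control) and cell division (gained in HIN1 stress). Residuals of libraries of the same number had r of -0.11 to 0.195 across groups, over 0.1 in 5 of 18 pairs, and 6 of 12 libraries were closest to their own number. The numbers were not taken as pairs, although library 3 had the highest chloroplast share in all 4 groups, and a shared experiment behind some numbers was not excluded. RLE factors gave 7225, 638, 779, 6207 and 36 genes, no filter 6886, 635, 783, 5909 and 48, and counts divided by 2 gave 7181, 622, 740, 6178 and 28. Of 960 values of the 62 results named by fold change, 895 were on the same side of the threshold with the same direction, 65 lost the call and 0 reversed. Of 4766 values of 304 results for list members, 4414 were the same, 343 lost the call, 9 gained it and 0 reversed. The 304 results include members of lists without a call, as were all 48 in the interaction. A gene called in neither fit was counted as the same even if its direction changed. For such genes the counts of same and reversed values therefore say little. In the interaction, AT1G26390 lost its call in 14 settings (highest adjusted p = 0.124), CYP71A12 with the block (0.0605), and AT2G43140 lost its call with the libraries numbered 1 and 2 only (adjusted p = 0.101), as CYP71A12 also did (0.0925). A single fragment can give a count of 2, which limits the precision of genes near the floor.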

Other observations

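The tests of this part, other than the splits of the libraries, were chosen after the results they bear on were seen. Gene families in the annotation, grouped by product name, were tested for an excess of higher genes in HIN1 (341 families of at least 10 members, background of 22344 genes, one-sided Fisher's exact test adjusted over families). At control 12 families passed, among them peroxidases (15 of 70 genes, adjusted p = 9.63e-09), chitinases (7 of 14, 1.27e-06), tau class glutathione S-transferases (8 of 27, 9.41e-06), glutamate receptors (5 of 19, 0.00227) and WRKY transcription factors (6 of 52, 0.0415). At stress 18 passed, among them cysteine-rich receptor-like kinases (10 of 33, 1.05e-05), peroxidases (14 of 70, 1.05e-05), defensins (8 of 21, 2e-05), glutamate receptors (7 of 19, 6.79e-05), WRKY transcription factors (10 of 52, 0.000228) and chitinases (5 of 14, 0.00141). For lower genes 0 families passed by this test in either comparison, and 4 at control and 9 at stress had an unadjusted p under 0.05. With 1 library left out, the WRKY family lost its call at control in 4 of 6 runs (adjusted p = 0.33 without HIN1 control library 3, 0.291 without WT control library 2, 0.228 without WT control library 1 and 0.195 without HIN1 control library 2), glutamate receptors without WT control library 3 (0.0566), and defensins at stress without WT stress library 1 (0.216) or HIN1 stress library 1 (0.0522). The other families named here passed in each of the 6 runs of their comparison. The number of families passing at control was 6 to 8 in 5 runs and 25 without WT control library 3. Root and root hair markers had positive log2 fold changes in 28 of 31 cases at control, and an effect of root content on the families there was not tested. Families hold similar sequences, so their genes are not independent.

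At 3 places picked from the named genes, several neighbors were called in the same direction in a comparison. Of 9 genes on chromosome 1 (4620101 to 4638330) with members of the DUF1262 family, 8 fell in WT stress, and 6 were higher in HIN1 at control and 6 at stress. Of 4 tested berberine bridge enzyme-like genes on chromosome 1 (9126737 to 9143336), 4 fell in WT stress, and 3 were higher in HIN1 at control and 4 at stress. Of 5 thalianol pathway genes on chromosome 5 (19417020 to 19461706), 3 were lower in HIN1 at stress, or 1 without HIN1 stress library 1 or 3, and AT5G47950 was not (0.14 ± 0.203). Without WT control library 3, 4 of the 5 rose in WT stress and 1 was higher in HIN1 at control. At control THAS1, the most changed of them, had a log2 fold change of -0.57 ± 0.185 (adjusted p = 0.13).

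Genes near silence in WT stress made up much of the difference at stress. Of 2032 tested genes below 0.5 CPM in WT stress, 309 were called and all 309 were higher in HIN1, while above 5 CPM 212 were called and 179 were higher. A level near 0 leaves little room for a lower value, so the direction is partly built in. The 309 genes averaged 0.373 (SD 0.0148) CPM in WT control, 0.139 (SD 0.0105) in WT stress, 1.18 (SD 0.0255) in HIN1 control and 1.35 (SD 0.135) in HIN1 stress. Of 2647 coding genes without a read in WT, 77.3% had none in HIN1 stress, where an even spread would leave 42.5%. These values argue against genomic DNA as the sole source of their reads. The even spread was scaled to the HIN1 stress reads of the same genes, so a lower level of genomic DNA was not excluded. Shared reads were argued against, since 3.24% of the 309 genes had over 10% of reads at several sites. Flower tissue was also argued against. The summed level of 11 flower markers in HIN1 stress was 0.872 of that in WT stress (8.35 against 9.58 CPM, SEP3 the highest at 3.6 CPM). Windows of 500 kb in which over 40% of the genes were pseudogenes were taken as pericentromeric, and no centromere positions were used. The tests of these windows and of pseudogenes are therefore not independent. Near-silent genes in pericentromeric windows were called more often than others (22% against 14.6%, odds ratio 1.64, Fisher's exact two-sided p = 0.0167). So were near-silent pseudogenes (22.2% against 14.4%, odds ratio 1.69, Fisher's exact two-sided p = 0.00645). A gene silent in WT passes the filter only through its level in HIN1, so these shares do not support relaxed silencing. Among the 1380 near-silent genes that passed the filter on the WT libraries alone, 136 were called higher, and the odds ratios were 0.739 (Fisher's exact two-sided p = 0.499) and 0.716 (Fisher's exact two-sided p = 0.426). These leave out the genes most silent in WT, so relaxed silencing was neither supported nor excluded.

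At both treatments 294 genes other than HIN1 were higher in HIN1, on all 5 chromosomes. A single transgene insertion acting on its neighbors could not account for them, since the fullest window of 500 kb held 11 of the 292 placed genes (3.77%), on chromosome 1 from 4561028. A larger share of root tissue at both treatments was argued against by the root and root hair markers. Their median log2 fold change at stress was -0.072 (quartiles -0.13 and 0.09). The lower quartile of the 294 genes was 1.08 at stress, which is partly built in, as they were selected as higher there. An effect of HIN1 itself and an effect of the single transformed line stay open, as there is 1 line.

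For the 4 pairwise comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each. The real counts were 7239 in WT stress, 633 at control, 785 at stress and 6219 in HIN1 stress, and the highest others were 1, 0, 6 and 2. The other splits put libraries of both real groups in each new group, which widens the spread where the groups differ. Their low counts are thus partly built in and give no chance level for the real counts.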
